A study of Homo sapiens with 2 samples.

How the data were processed

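Total RNA of UM-UC-3 and SV-HUC-1 cells was extracted with TRIzol, amplified into Cy3 cRNA by random priming and hybridised to 1 array per line, per the labels' protocols. The lines were grown in different media (DMEM for UM-UC-3 and F-12K for SV-HUC-1, each with serum), so medium and line were not separated. Both arrays were read in the same scan, per the file headers, so the lines do not differ by scan.

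Spot intensity values were produced with Agilent Feature Extraction 11.0.1.1 in its one-colour protocol, per the file headers, which subtracts background and removes spatial trends within an array. Flags of 0 or 1 for saturation, outliers and signal well above background come from the same program, per the file headers. The submitters' processing notes also name limma without a role. The deposited table of the series lists 5010 filled rows for 4814 probes, 196 of them repeats, beside 8231 blank rows. Its raw intensity columns, as deposited by the authors, equal the scanner's processed signal with values under 5 set to 5, with a largest relative difference of 1.2e-06. Its normalized columns, deposited by the authors on a log2 scale as judged from the values, have medians of 5.51 (UM-UC-3) and 5.49 (SV-HUC-1). The authors' method is not given in the sources used here. Quantile normalization of the log2 processed signal gave differences within a median of 0.000273 of theirs. The table holds SELNC and SUPERLNC probes only, and each of the 4812 such probes found well above background on at least 1 array is listed.

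From the scanner files, log2 processed signal minus the 75th percentile of each array was computed over non-control probes other than those named negative. The offset between the arrays was 0.43 on the log2 scale. Spots with an outlier flag (9 for UM-UC-3, 15 for SV-HUC-1) were left out, which removed 4 probes altogether, and spots of one probe were averaged. A probe counted as well above background by a majority of its usable spots. Control spots and 20 custom probes of unstated content were kept out of the counts, which leaves 14839 probes, 61.2% of them measured on both arrays. The comparison was UM-UC-3 minus SV-HUC-1 with a threshold of 2-fold, and no test across samples was possible. Probes above background on 1 array were given as bounds: the bright array's value against the higher of the dim probe's own value and the lowest signal among probes well above background on the dim array. Those floors were 8.48 units for UM-UC-3 and 10.0 for SV-HUC-1 before scaling. Shares have exact (Clopper-Pearson) 95% intervals over probes, which cover counting error only. With arrays, their number limits the precision.

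Probe IDs of the 5 custom series carry no gene name, and their positions and neighbouring genes are not analysed here. The 50 catalogue probes carry RefSeq accessions, and all 50 matched 1 symbol in a table of the GRCh38.p14 assembly. The array grid is annotated on hg19, so no coordinates are given. Named genes followed a rule fixed before the data were examined: up to 6 genes each way with at least a 2-fold difference of one sign under the processed signal, normexp with quantile and the authors' values, up to 4 bounds each way, and members of fixed lists. The authors' values do not cover the named probes, so the first 2 value sets decided. The parts of the rule on lncRNA genes, on LINC00162 with its neighbour PTTG1IP and on lncRNA and gene pairs could not be applied without names.

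Gene lists (21 lists, 426 genes) were fixed before the data were examined, and a list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins. Alternatives were normexp (limma, offset of 50) followed by quantile normalization, quantile normalization alone, median centring, the authors' values, other filters on dim and outlier spots, thresholds of 1.5-fold and 4-fold, and bright probes only, which changed one choice at a time except for normexp with quantile and for the authors' values, which also narrow the probes to the SELNC and SUPERLNC series. The scanner files used here give a median but no mean spot signal, so normexp took the median signal with the median local background. The normexp offset of 50 units is added to every signal, which by itself shrinks differences of dim probes. Removal of a lowess trend (span of 0.3), the counts at 16-fold, other floors for the bounds, the error by brightness and the omission of probes of mean log2 signal of 16 or more were added after the data were seen. Medians of the differences in 8 blocks of rows ranged from -0.06 to 0.11 and in 8 blocks of columns from -0.09 to 0.10.

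The comparison was tested on simulated data made from the real SV-HUC-1 signals and the scanner's own error. With 9080 probes, all 50 probes simulated at 3-fold were past 2-fold (100%), as were all 50 at 4-fold and all 50 at 8-fold. At 1.5-fold 4% of 50 were, and of 8880 unchanged probes 0.045% were. The simulation holds no spread between cultures. It also holds few changed probes, a single offset shared by all probes and the real detection calls, so the scaling suited it by construction. Its rates may therefore be too favourable for the real arrays. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.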

Results

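RNA from 2 human cell lines was read, with 1 array each, on a custom one-colour array for long noncoding RNAs (lncRNAs) of super-enhancers, the large enhancer clusters that drive genes of cell identity. UM-UC-3 is a bladder cancer line and SV-HUC-1 is an immortalised line of urothelium, the epithelium that lines the urinary tract. The question posed in the series description was which super-enhancer lncRNAs differ between the cancer line and the urothelial control. Each array carried 15183 non-control spots for 14923 probes, and no spot was saturated. On the UM-UC-3 array 10336 spots lay well above background, and on the SV-HUC-1 array 9891 did. The UM-UC-3 array was also brighter as a whole, with a 75th percentile of 239 intensity units against 178. Among the 180 spots named as negative on each array, 10 were called well above background for UM-UC-3 (5.56%, 95% interval 2.70 to 9.98) and 9 for SV-HUC-1 (5.00%, 2.31 to 9.28). With 1 array per line, no difference has a replicate check. Every value below describes these 2 arrays, and errors are the technical error within an array.

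The deposited table of this super-enhancer lncRNA series lists only probes with SELNC and SUPERLNC IDs, called lncRNA-series probes here, and most of those measured lay at similar levels in both lines. What these IDs stand for is not given in the sources used here. Of 3788 probes well above background on both arrays, 3185 (84.1%) were within 2-fold, 255 (6.73%, 95% interval 5.95 to 7.58) were at least 2-fold higher in UM-UC-3 and 348 (9.19%, 8.29 to 10.2) were at least 2-fold lower. The median log2 difference was -0.02. The strongest lncRNA-series differences lay on the lower side, with 22 probes at least 16-fold lower in UM-UC-3 and 1 at least 16-fold higher (4 and 1 under normexp background correction followed by quantile normalization). On the lower side, ASHG19SELNC2A100016153 read 16.3 intensity units in UM-UC-3 and 1810 in SV-HUC-1, 149-fold lower in UM-UC-3 after scaling (log2 difference -7.22). ASHG19SELNC2A100500346 was 101-fold lower, at 42.3 against 3175 units (-6.66). In the other direction, ASHG19SELNC2A101070378 was 42.8-fold higher in UM-UC-3, at 2267 against 39.4 units (5.42), and ASHG19SELNC2A100915109 was 14.2-fold higher, at 1025 against 53.8 units (3.83). With normexp and quantile the log2 differences of these 4 probes, in the order given, were smaller, at -4.90, -5.17, 4.35 and 3.07, and the order of the 2 lower ones turned. The files pair none of these IDs with a gene, so the lncRNAs are given by probe ID.

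A further set of lncRNA-series probes was called well above background in 1 line only. In UM-UC-3 57.7% of the 7749 SELNC and SUPERLNC probes were well above background and in SV-HUC-1 53.3% were. In UM-UC-3 only, 685 probes passed, against 339 in SV-HUC-1 only. Of the spots named as negative, 5.56% (UM-UC-3) and 5.00% (SV-HUC-1) also passed, so some of these calls may be false. Taken as bounds against the dim array's detection floor, 93 of the 685 were at least 2-fold higher in UM-UC-3, while 268 of the 339 were at least 2-fold lower. This contrast depended on the floors and the scaling, because the floor after scaling lay lower on the UM-UC-3 array (-4.82 against -4.15 on the log2 scale). With the higher floor used for both arrays the counts were 93 and 173, with quantile normalization 123 and 222, and by the authors' values, taken without a bound, 315 and 308. The excess of lower over higher probes at 2-fold did not hold under every scaling. Quantile normalization, which moved the median difference of all measured probes from 0.01 to 0.13, gave 315 lncRNA-series probes higher and 290 lower. A set of 247 lncRNA-series probes was 2-fold apart in the same direction in the scanner signal, in the normexp and quantile signal and in the authors' normalized values, 119 of them higher in UM-UC-3 and 128 lower.

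**Figure D1:**
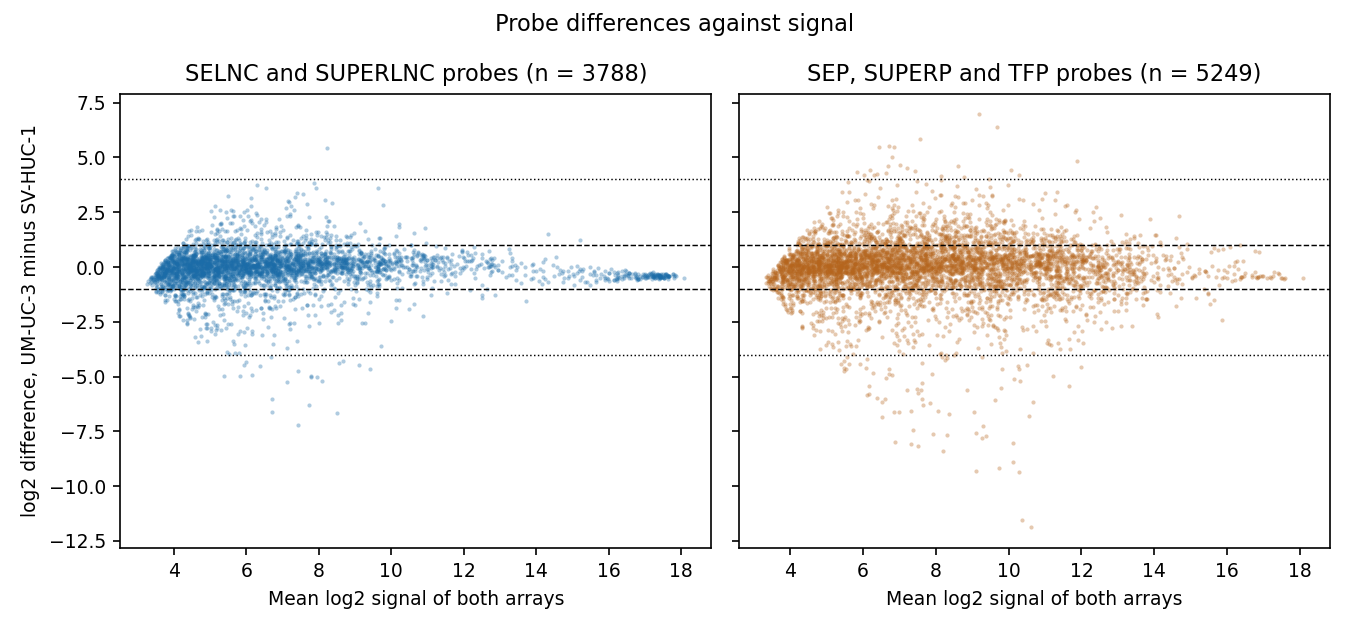
Log2 difference (UM-UC-3 minus SV-HUC-1, scaled to the 75th percentile of each array) against the mean log2 signal of both arrays for each probe well above background on both, with 3788 SELNC and SUPERLNC probes on the left and 5249 SEP, SUPERP and TFP probes on the right. Dashed lines mark 2-fold and dotted lines 16-fold, and 22 lncRNA-series probes lie beyond 16-fold on the lower side against 1 on the upper side.

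Probes of the SEP, SUPERP and TFP series, which the deposited table leaves out, differed more often between the lines than the lncRNA-series probes did. Of 5249 measured, 742 (14.1%, 95% interval 13.2 to 15.1) were at least 2-fold higher in UM-UC-3 and 785 (15.0%, 14.0 to 15.9) at least 2-fold lower, so 29.1% (27.9 to 30.3) lay outside 2-fold, against 15.9% (14.8 to 17.1) of the lncRNA-series probes. Of 2912 SEP probes 16.7% were lower and 13.5% higher, a balance that turned under quantile normalization (421 lower, 452 higher). Of 996 TFP probes 15.2% were higher and 11.3% lower, and the higher ones outnumbered the lower ones under each of the 4 other scalings. Of 1341 SUPERP probes 14.8% were higher and 13.8% lower, which turned with a lowess trend removed (182 higher, 195 lower). At 16-fold or more, 75 probes of these series were lower in UM-UC-3 and 24 higher. What the SEP, SUPERP and TFP series stand for is likewise not given. With normexp and quantile together, the shares outside 2-fold were 19.3% for these series and 6.60% for the lncRNA series.

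**Figure D2:**
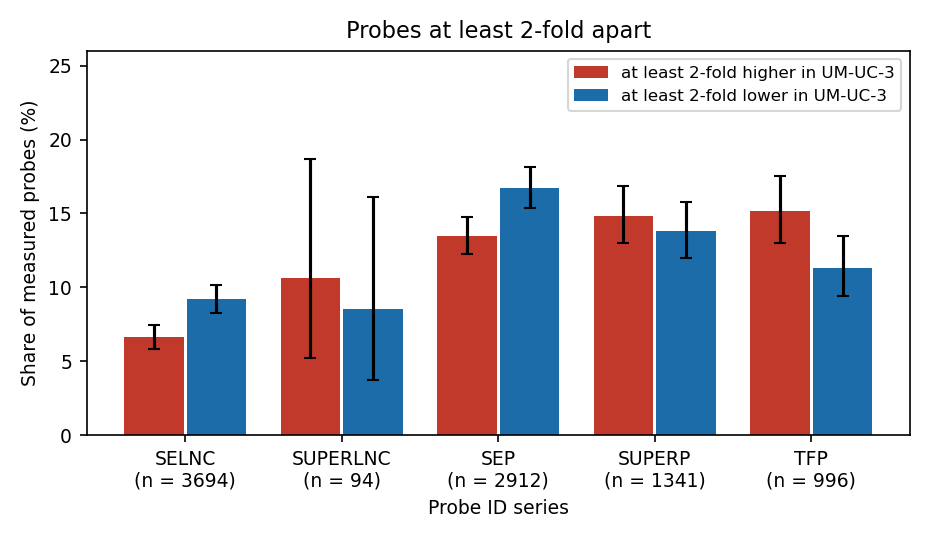
Share of measured probes (percent) at least 2-fold higher or lower in UM-UC-3 for each probe ID series, with n the probes well above background on both arrays and error bars the 95% exact binomial interval over probes, which covers counting error only. SELNC bars stand at 6.63% higher and 9.20% lower, and SEP bars at 13.5% higher and 16.7% lower.

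Among the 50 genes that could be named, the cell cycle gene CCNA2 and the DNA replication gene PRIM1 showed the largest measured excess in UM-UC-3. CCNA2, which encodes cyclin A2 of S phase and mitotic entry, was 4.89-fold higher (log2 difference 2.29 ± 0.04, SE from 3 spots per array). PRIM1, the catalytic subunit of DNA primase, was 3.55-fold higher (1.83 ± 0.03). KIF20A, a kinesin of cytokinesis, was 3.41-fold higher (1.77 ± 0.03), and ABRAXAS1, a scaffold protein of a DNA damage response complex, was 3.48-fold higher (1.80 ± 0.05, with 2 usable spots on the SV-HUC-1 array). ERGIC2, a protein of the compartment between endoplasmic reticulum and Golgi, was 2.61-fold higher (1.38 ± 0.03).

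On the lower side stood RND3, which counters actomyosin contraction, and MOCOS, the sulfurase of the molybdenum cofactor. RND3 was 5.50-fold lower in UM-UC-3 (log2 difference -2.46 ± 0.01) and MOCOS 3.95-fold lower (-1.98 ± 0.06). For 3 genes only SV-HUC-1 gave a signal well above background, so their differences are bounds. SAA4, a constitutive serum amyloid protein, was at least 22.3-fold lower in UM-UC-3. PLA2G4A, the cytosolic phospholipase that releases arachidonic acid, was at least 10.3-fold lower, and LOX, the lysyl oxidase that cross-links collagen and elastin, at least 3.80-fold lower. These bounds hold for the processed signal only. With normexp and quantile the log2 differences were -1.94 for SAA4, -1.16 for PLA2G4A and -0.55 for LOX, the last within 2-fold. That method adds an offset of 50 units, above the UM-UC-3 signals of these genes (1.88, 2.04 and 1.85 units in that order). Such an offset shrinks differences of dim probes, so the smaller values cannot decide whether the bounds fail. LOXL2, a relative of LOX, was instead well above background in both lines and differed by 0.44 ± 0.02, a gene picked out after its value was seen. ZAP70, a T cell kinase, was called above background in UM-UC-3 only, on 2 of 3 spots and near the floor, and has no fold.

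In all, 43 of the 50 named genes were measured on both arrays, of which 7 were at least 2-fold higher in UM-UC-3, 6 at least 2-fold lower and 30 within 2-fold, and their median difference was 0.44. The remaining genes past 2-fold, named here after their values were seen, did not keep that size with normexp and quantile. TCF7, a transcription factor of the Wnt pathway, was higher by 1.61 on the log2 scale (0.89 with normexp and quantile), and POLR2A, the largest subunit of RNA polymerase II, by 1.19 (0.98). CPS1, the first enzyme of the urea cycle, read -2.74 (-0.73 with both) from a dim signal in UM-UC-3 of 9.18 units. LMO2, NMI and CHAF1B lay close to the threshold, at -1.03, -1.02 and -1.01.

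**Figure D3:**
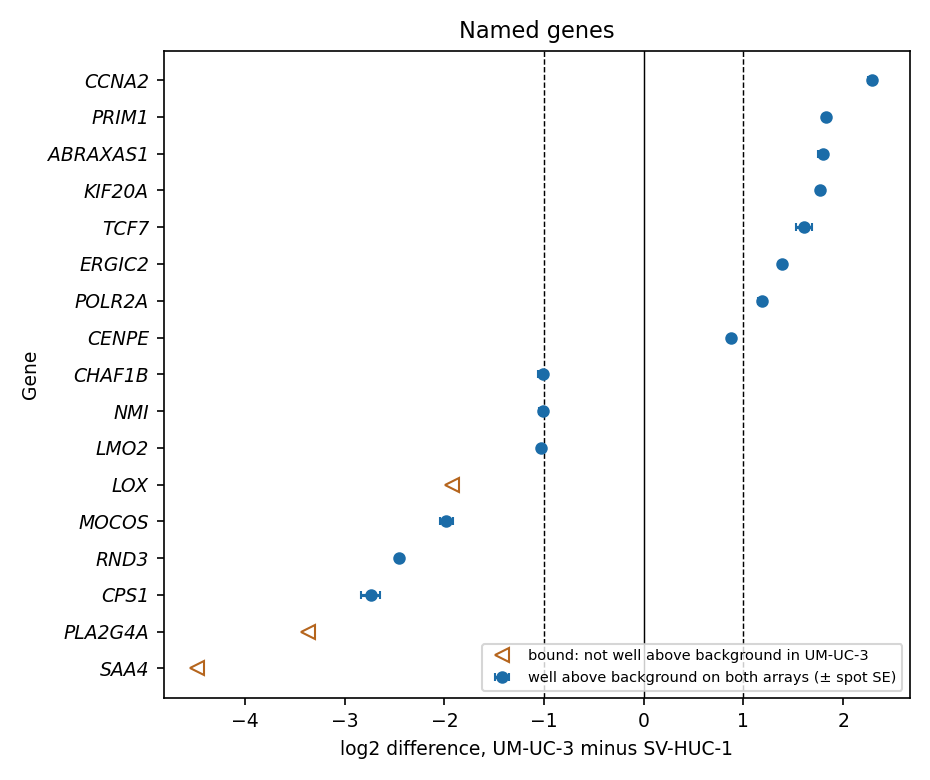
Log2 difference (UM-UC-3 minus SV-HUC-1) of the named genes at least 2-fold apart, of CENPE and of the 3 genes with bounds, with filled circles for genes well above background on both arrays (bars, SE from the spots of each probe, which is technical error only) and open triangles for the smallest difference the detection floor of the processed signal allows. CCNA2 lies furthest right at 2.29 and the SAA4 bound furthest left at -4.48.

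Of the 21 gene lists fixed beforehand, 3 held a named gene of this array. The list of E2F targets and replication genes was represented by CCNA2 alone, whose difference of 2.29 lay at percentile 98.3 of 10000 random lists of matched signal. The mitosis list was represented by KIF20A (1.77) and CENPE, a kinetochore kinesin (0.88 ± 0.01), and their median of 1.32 lay at percentile 95.3. One of these 2 mitosis genes was past 2-fold and both were higher in UM-UC-3. These percentiles are among all measured probes, while the named genes as a set had a median of 0.44. The mesenchymal list was represented by LOX, with its bound of at least 3.80-fold lower in the processed signal and -0.55 on the log2 scale with normexp and quantile. The other 18 lists, which covered uroplakins and urothelial differentiation, epithelial junctions, basal keratinocyte genes, HOX clusters, p53 targets, interferon and cytokine genes, hypoxia, lncRNAs known from bladder cancer and markers of fibroblasts, endothelium and leukocytes among others, had no named gene here, so contaminating cell types could not be examined.

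Over all 9080 measured probes of every series, 1004 (11.1%) were at least 2-fold higher in UM-UC-3 and 1139 (12.5%) at least 2-fold lower. The excess of lower probes was largest among the dimmest 1816 probes, with 66 higher and 212 lower. The floor after scaling lay lower for UM-UC-3 (-4.82) than for SV-HUC-1 (-4.15). That leaves more room for a lower than a higher call among such probes, so part of the excess may be built in. The 7264 brighter ones together gave 938 higher and 927 lower, but their balance changed with signal. In groups of 1816 from dim to bright it was 200 higher and 227 lower, 252 and 232, 307 and 222, and 179 and 246. The balance turned with quantile normalization, to 1177 higher and 972 lower on its own and to 665 and 609 after normexp. The error of a difference between single spots was 0.117 on the log2 scale over the named-gene probes well above background, printed in 3 spots, but it depended on brightness. It was 0.07 for probes of log2 signal of 7 or more on both arrays and 0.39 for probes dimmer than that on both, the latter from 3 UM-UC-3 and 5 SV-HUC-1 probes. The 0.39 is probably too low. Its UM-UC-3 part, a pooled SD of 0.33, fits a pool of spots well above background only. CPS1 and ZAP70 each had 2 of 3 such spots in UM-UC-3, and their SDs over all 3 spots were 0.16 and 1.02. SERPIND1 had 0.02 from 2 usable spots. Of the measured probes 4126 (45.4%) were dim on both arrays, where 3 times the error (1.18) lies above the 2-fold threshold. With the error matched to brightness, 1959 of the 2143 probes past 2-fold exceeded 3 times their error. Probes not dim on both arrays all did so by construction, because 3 times their error lies below the 2-fold threshold. Only the 655 dim ones could fail, and 471 of them exceeded it. A larger dim error would lower both counts. The error says nothing of the spread between cultures. The authors' normalized values for the 3788 lncRNA-series probes correlated with the scaled differences at r = 0.993 across probes, probes not being independent replicates. Both derive from the same scanner signal, so a close match was built in and is no independent check. The authors' values gave 315 of these probes higher and 290 lower, including all 255 and 289 of the 348 found with the 75th percentile scaling. Over all 4814 listed probes, those detected on 1 array included, they gave 630 higher and 599 lower.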

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

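The tests on the 16-fold counts and on the very bright probes were set up after those counts and that group of probes had been seen, though before the values of the tests themselves. In addition, the wording of the detection pattern was widened to take in the 16-fold counts after its detection tests had been run. No biological replicate exists, so a difference between the lines themselves was not tested.

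Signal appeared among 20 custom probes of unstated content that no comparison used. Of the 19 well above background on both arrays, 16 were within 2-fold and 1 was lower in UM-UC-3, while custom probe 3 was higher by 2.35 and custom probe 10 by 1.67 on the log2 scale.

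UM-UC-3 had more probes well above background, yet the strongest differences were mostly lower in UM-UC-3, with 97 probes at least 16-fold lower against 25 higher. Above 1 signal minimum (12.9 units), the ratio of probes found on UM-UC-3 only to probes found on SV-HUC-1 only was 1.24 before scaling and 0.526 (95% interval over probes 0.473 to 0.585) after. Dividing a whole array by 1 factor lowers its detections in any case, so a brighter array and more expressed transcripts in UM-UC-3 cannot be told apart as sources of the extra detections. A deeper floor does not account for the 16-fold excess, since the ratio of lower to higher probes was 3.51 (2.63 to 4.74) with the same floor on both arrays. The excess also stayed under 4 other scalings, with a ratio of 3.17 (2.08 to 4.95) at its lowest. Under those scalings the median of all differences lay between -0.01 and 0.13, so they could hardly shift counts at 16-fold and test scaling only weakly. What stays open is whether transcripts strong in SV-HUC-1 and weak in UM-UC-3 belong to the lines, their media or these single cultures.

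Probes of the SELNC and SUPERLNC series were 2-fold apart less often than SEP, SUPERP and TFP probes (15.9% against 29.1%). Their lower signal is an unlikely source, because reweighting to the signal distribution of the other series gave 15.1% (13.9 to 16.4). The filter on dim probes could not be cleared as a source. With bounds counted 964 of 4812 and 1892 of 5970 probes were 2-fold apart, a ratio of shares of 1.58 (1.48 to 1.69). A bound is a minimum, so that count misses some differences of probes detected on 1 array. Such probes numbered 685 and 339 in the lncRNA series against 413 and 308 in the others. Without bounds the shares were 25.1% and 34.1%, closer but in the same order. Very bright probes near the same unscaled level on both arrays were left out in another test, and the ratio was then 1.77 (1.63 to 1.93). They made up only 3.59% of the measured lncRNA-series probes, so their omission could hardly move the ratio. That test shows only that the group is too small to account for the contrast. Probe design, cross-hybridisation and the classes of RNA behind the ID series stay open and were not tested.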

How the results depend on the processing

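Lowess trend removal, the 16-fold counts, other floors for probes detected on 1 array, the error by brightness and the omission of very bright probes were chosen after the data were seen. No paired analysis was possible because each group holds 1 array. Of 142 alternative values for 19 results, 98 stayed within the main value's error or within 1.5 times its count, 44 moved further and 0 reversed. The authors' values cover fewer probes than the counts they were scored against, so their moves do not reflect scaling alone. Counts, shares, percentiles and spreads have no sign, so only the log2 differences of lists and genes could reverse. The balance of higher and lower probes was not scored, and it did turn. It went to 1177 higher and 972 lower with quantile normalization, and also turned with normexp and quantile and among bright probes. For the 8 genes measured and named by the rule, 45 of 55 alternatives stayed within the larger of the gene's spot error and 0.117. Of the 55, 48 were at least 2-fold. These counts overstate stability, because changes of filter leave a gene's own value as it was. A 2-fold difference with normexp and quantile was also required by the naming rule for all of these genes except CENPE. Percentiles of the lists ranged from 95.1 to 98.7. Probes 2-fold higher and lower numbered 1004 and 1139. They were 665 and 609 with normexp and quantile, whose offset shrinks differences of dim probes (other causes were not tested). With the authors' values they were 315 and 290 among 3788 probes measured on both arrays, and 630 and 599 over all 4814 listed. They were 1648 and 2287 with no filter, 1861 and 1954 at 1.5-fold, 243 and 420 at 4-fold, and 472 and 429 among bright probes. With probes above background on at least 1 array, 1487 were higher and 1768 lower. The SELNC and SUPERLNC share of 15.9% was 6.60% with normexp and quantile, 25.1% above background on either array and 21.4% unfiltered, and the SEP, SUPERP and TFP share of 29.1% was 19.3%, 34.1% and 32.1%. Probes 16-fold higher and lower numbered 7 and 46 with normexp and quantile. They were 93 and 369 with either looser filter, which admits signals without a measured level. The authors' values gave 1 and 22 among the 3788 lncRNA-series probes, the same counts as the 75th percentile scaling of those probes. The error of a single difference was 0.208 from the scanner's estimate and 0.395, probably too low, from spots of dim probes, against 0.117 over all brightness. Past 3 times it were 36.3% with the scanner's estimate, 46.0% by brightness and 60.9% with 0.117. Signal over background limits dim probes, but the balance did not follow brightness alone. Among the 1816 dimmest (9.65 to 29.6 units), where the unequal floors favour lower calls, 3.63% were 2-fold higher and 11.7% lower. In the next to brightest group of that size (202 to 894 units) 16.9% were higher and 12.2% lower. In the brightest group 9.86% were higher and 13.5% lower, again with more lower ones. Positional lncRNA classes, lncRNA and gene pairs, chromosome regions, the median over a gene's probes (1 probe per gene) and the authors' values for lists were not run.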

Other observations

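The grouping of genes in the next paragraph and the tests on it were chosen after the values were seen, as was the signal limit for very bright probes.

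Of the named genes, 18 measured ones were picked by hand as acting in DNA replication, repair or chromosome segregation, and the group need not be complete. In UM-UC-3 12 of the 18 were higher and 6 lower, with a median log2 difference of 0.52. Beside CCNA2, PRIM1, ABRAXAS1 and KIF20A, which were past 2-fold, DSCC1 (cohesion establishment at the replication fork) was higher by 0.98 ± 0.03, the helicase WRN by 0.73 ± 0.02 and the replication licensing regulator DTL by 0.57 ± 0.07. In the other direction stood CHAF1B, a chromatin assembly subunit, at -1.01 ± 0.04, the exonuclease EXO1 at -0.54 ± 0.02 and SMC6 of chromosome maintenance at -0.31 ± 0.01. The group's median lay at percentile 98.4 of random probe lists of matched signal, but the 25 other named genes, with a median of 0.41, lay at percentile 98.8. Among random lists drawn from the named genes the group lay at percentile 77.7, so it did not stand apart from them. As the group was put together after its values were seen, these percentiles describe it and decide nothing about a trend with signal or a shift of the catalogue probes.

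A group of very bright probes read nearly the same on both arrays before scaling. Of the measured SELNC and SUPERLNC probes, 136 (3.59%) had a mean log2 signal of 16 or more, with median signals of 152801 units for UM-UC-3 and 148676 for SV-HUC-1. Their median unscaled difference was 0.02, and it was -0.40 (SD 0.10) after scaling, with 0 of them 2-fold apart. Among SEP, SUPERP and TFP probes 42 (0.80%) were as bright, with a median scaled difference of -0.41 and 1 past 2-fold. No spot was called saturated.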
